A study of Mus musculus with 14 samples.

How the data were processed

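The samples are bulk RNA-seq libraries of CD4+ T cells sorted from the cecum lamina propria of female DNMAML F/F mice with or without Mcpt8-Cre, naive or on day 14 of T. muris infection. Per the labels' protocols, total RNA was reverse transcribed and amplified to full-length cDNA with the SMART-Seq v4 kit, and libraries were made with the NexteraXT kit, which does not mark strand. No molecular identifiers are named, so intervals and floors cover counting error only. Groups were taken from the titles and the genotype and treatment characteristics. The treatment protocol names Cre-negative mice for all samples, and the genotype characteristic was used. Of 14 labelled samples, 12 had a column in the tables, 3 per group, and 2 naive samples were not analysed here. The design had assumed 14 libraries and was otherwise kept. Replicates are separate samples per the labels, each of 1 or 2 mice, and pairs of replicates differed by far more than counting noise.

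The authors' counts table held whole-number gene counts. Per the submitters' processing notes, STAR 2.4.2a, HTSeq, Picard and DESeq2 were used with GRCm38 (mm10); the role and order of these tools, the gene annotation and the strand setting were not given in the sources used here. The deposited normalized table (signal) held the same 53465 genes divided by 1 size factor per library. The factors equalled DESeq2's median of ratios computed here from the counts, with a largest relative gap of 1.24e-11. Il4, Il5 and Il13 were the exceptions described in the results. In total, 4103 genes had no symbol. GENCODE release M21, of build GRCm38, matched 53274 of the 53465 IDs and was used for coordinates, gene types and exonic lengths.

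Among named genes, Hdc (ENSMUSG00000027360) lies on chromosome 2 at 126593667 to 126619299, Lars2 (ENSMUSG00000035202) on 9 at 123366927 to 123462666, Tnfaip3 (ENSMUSG00000019850) on 10 at 19000910 to 19015657, Cox8a (ENSMUSG00000035885) on 19 at 7215153 to 7217616, Cmtr2 (ENSMUSG00000046441) on 8 at 110215665 to 110224486, Slc25a29 (ENSMUSG00000021265) on 12 at 108825873 to 108835883, Tmem106a (ENSMUSG00000034947) on 11 at 101582242 to 101591788, Cybb (ENSMUSG00000015340) on X at 9435252 to 9487771 and Zfp574 (ENSMUSG00000045252) on 7 at 25072567 to 25083492, in GRCm38.

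Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, its filter on low counts, which left 12633 genes, and robust quasi-likelihood fits with 1 coefficient per group over the 12 libraries. There were 5 contrasts, namely infection within each genotype, genotype within each infection state, and the difference of the infection effects. P values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. Of 35 gene lists of T cell programmes, metabolism, stress and other cell types, 33 had at least 3 tested genes and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 33 lists of each contrast, and again with an estimated correlation. The eosinophil list had 1 tested gene and the erythroid list 2, so neither was tested. In the list results, "adjusted over the list alone" means that only the list's genes were adjusted for. CPM values used the TMM library sizes. Single measures per library were compared by exact permutation tests (two-sided), which cannot go below 0.1 with 3 against 3. Folds against a group at 0 used a floor of 3 counts over the group. The normalized values were used for limma-trend with a pseudocount of 1. Low counts limit the precision, and a count of 0 in a library allows up to 3 counts.

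The design, the tests, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. Named genes were, per comparison, the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 2 and no overlap between the groups, leaving out unnamed gene models and receptor segments. Where fewer than 5 passed, the 5 with the smallest p were named as not passing. In each list up to 2 called members per direction were named, and 20 genes of T cell identity and function were always examined. Of these, 1 is not reported here. Further list members named as examples are among the 4 with the smallest p in the list's direction, or passed over the list alone, and were chosen after their values were seen. So were Atp5f1a and Atp5f1b, Kit and the basophil markers.

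Alternatives were DESeq2's size factors in edgeR, no filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with quality weights, fits of the compared groups alone, a replicate block, the normalized values, an adjusted p of 0.1 and leaving out each library in turn. Removing the 2 libraries of lowest complexity and exchanging the infected values of Il4, Il5 and Il13 between genotypes were added after seeing the data. So was the removal, from each library, of a smooth trend of log2 CPM on exonic length, applied to the genes and to the list tests. The tests were first run on 12 simulated libraries over 12633 genes, drawn from each gene's mean and spread over the 12 real ones. Changes were planted in the infected Cre-positive libraries only, in genes with a mean of at least 4 CPM. The draws held no library of low complexity. Between naive and infected Cre-positive libraries the tests recovered 12 of 100 genes changed 2-fold and 50 of 100 changed 4-fold. There were 2 calls among 12413 unchanged genes and 0 in an unchanged comparison.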

Results

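RNA was sequenced from CD4+ T cells sorted from the lamina propria of the mouse cecum, either before infection or 14 days after infection with Trichuris muris, a whipworm that lives in the cecum. All mice carried a floxed allele of DNMAML, a dominant-negative protein that blocks transcription driven by Notch receptors. The Cre-positive mice also carried Mcpt8-Cre, which is expressed in basophils. The series asks how Notch signalling in basophils bears on intestinal CD4+ T cells during helminth infection. Because DNMAML is switched on in basophils, no gene of the sorted T cells checks the genotype labels. There were 3 libraries in each of 4 groups, namely naive Cre-negative, naive Cre-positive, infected Cre-negative and infected Cre-positive mice. A further 2 labelled naive libraries were not analysed here. Per the labels, each library held cells of 1 or 2 female mice. Total counts ran from 2553591 to 6741492 per library. Levels below are CPM, counts scaled to the effective library size, as mean ± SD with n = 3 per group, and log2 fold changes are given ± SE. This SE is the absolute log2 fold change divided by the square root of edgeR's F statistic. It is thus derived from the test and is no separate measure of precision.

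The sorted cells carried the transcripts of CD4+ T cells in every group. Cd4 lay at 1419 ± 248 CPM in naive Cre-negative, 1194 ± 153 in naive Cre-positive, 1176 ± 133 in infected Cre-negative and 954 ± 119 in infected Cre-positive libraries. Cd3e, a chain of the T cell receptor complex, lay at 572 ± 42.2, 479 ± 26.1, 545 ± 82.6 and 495 ± 86.2 CPM in the same order. Foxp3, the transcription factor of regulatory T cells, reached 644 ± 332, 462 ± 28.6, 488 ± 128 and 549 ± 196 CPM.

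The infected Cre-positive libraries held fewer genes than the infected Cre-negative and naive Cre-positive ones, without overlap, and a higher mitochondrial share than every other library. In genes they overlapped with the naive Cre-negative libraries, which include the library with the fewest. At the depth of the smallest library, 13405 ± 728 genes were expected in them, against 15007 ± 385 in infected Cre-negative, 14460 ± 235 in naive Cre-positive and 14085 ± 1590 in naive Cre-negative libraries. The exact permutation test of infected Cre-positive against infected Cre-negative libraries gave p = 0.1 (two-sided), the smallest that 3 against 3 allows. Mitochondrial transcripts made up 2.72 ± 1.26% of the counts in infected Cre-positive, 1.32 ± 0.513% in infected Cre-negative, 0.703 ± 0.0825% in naive Cre-positive and 0.584 ± 0.201% in naive Cre-negative libraries. Epithelial marker genes held 0.130 ± 0.0845%, 0.0456 ± 0.0266%, 0.0138 ± 0.0148% and 0.0124 ± 0.00611% in the same order. Infected Cre-positive replicate 0 and naive Cre-negative replicate 2 had the fewest genes at equal depth, 12565 and 12251. On the principal components, infected Cre-positive replicate 0 lay far out at 162 on the first, and infected Cre-positive replicate 1 and naive Cre-negative replicate 2 at -113 and 97.3 on the second.

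**Figure D1:**
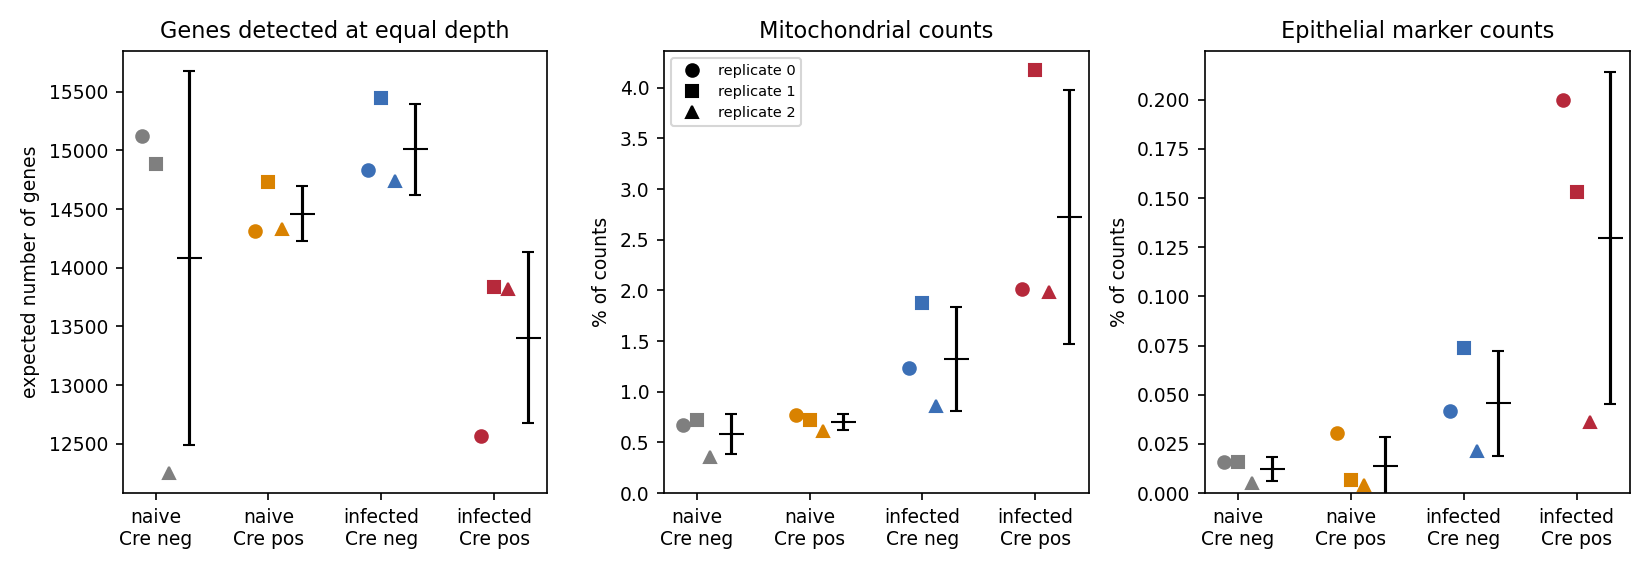
Expected number of genes at equal depth (left), mitochondrial counts in % (middle) and epithelial marker counts in % (right) for each of the 12 libraries by group, with symbols for the replicate number and bars for mean ± SD of 3 libraries. Infected Cre-positive libraries hold 12565 to 13833 genes, below the 14743 to 15449 of infected Cre-negative libraries.

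Il4, Il5 and Il13, the signature cytokines of type 2 helper T cells, need a caution that applies wherever they are named here. A table of raw counts and a table of normalized values were both used. Their ratio equalled 1 size factor per library, within a relative tolerance of 1e-06, for 53462 of the 53465 genes. Values at 0 in both have no ratio and were passed as equal. Of the 53465 genes, 23556 had a count in any library and 21059 in any infected library. The 3 exceptions were Il4, Il5 and Il13. In the infected libraries, 18 of 18 of their ratios equalled the factor of the same-numbered library of the other genotype, and 0 equalled the library's own factor. In the naive libraries, 7 of 7 nonzero values gave the library's own factor. The direction of the genotype difference in these 3 genes is therefore undetermined from the tables. As deposited, Il4 had 290, 50 and 178 counts in infected Cre-negative replicates 0, 1 and 2, and 100, 83 and 156 in the infected Cre-positive ones. Il5 had 51, 51 and 70 against 4, 28 and 24 counts, and Il13 had 24, 18 and 26 against 3, 6 and 5.

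**Figure D2:**
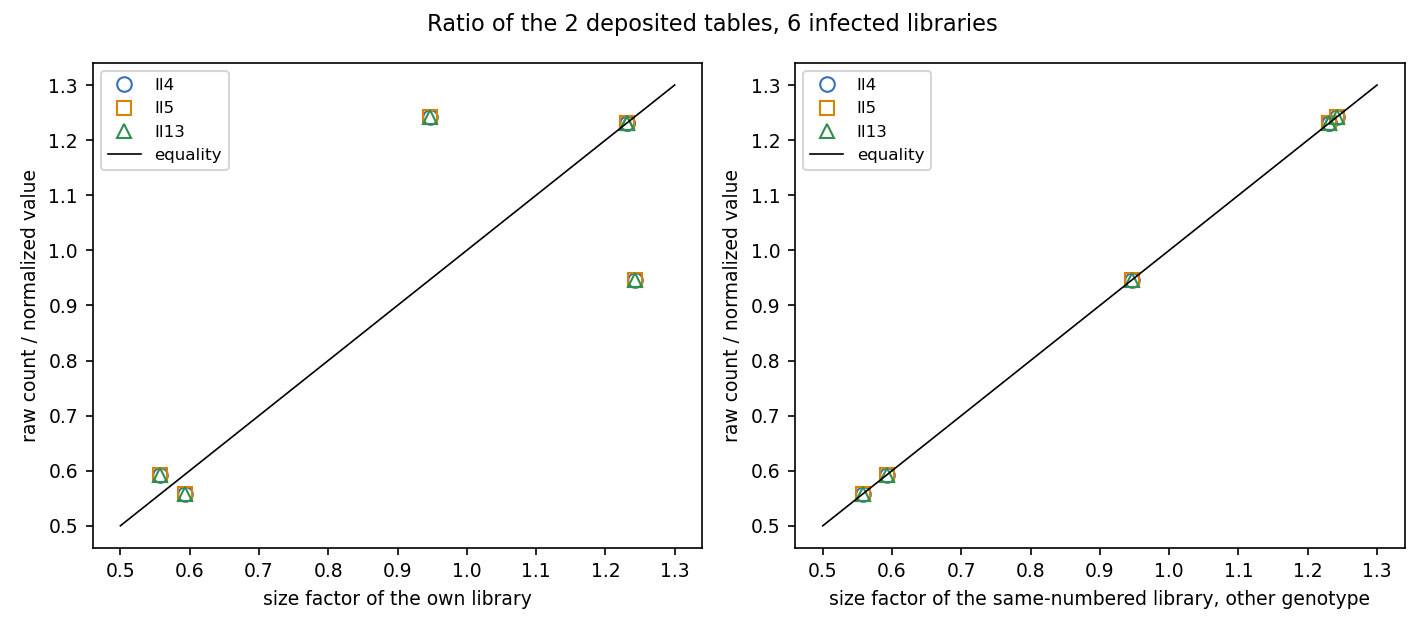
Raw count divided by normalized value for Il4, Il5 and Il13 in the 6 infected libraries, against the size factor of the library itself (left) and of the same-numbered library of the other genotype (right), with the line of equality. All 18 ratios lie on the line on the right and 0 lie on it within the tolerance on the left.

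The first comparison asks what infection changes in the cecal CD4+ T cells of Cre-negative mice, whose basophils keep Notch signalling. Transcripts induced by interferon gamma were higher after infection as a list. All 24 measured members had a positive log2 fold change, with a median of 0.67, and 13 rose when adjusted over the list alone, while 0 rose and 24 did not pass over all genes. Among them, Iigp1, an interferon-inducible GTPase that restricts intracellular microbes, went from 90.6 ± 13.7 to 237 ± 67.4 CPM (log2 1.39 ± 0.317). Tgtp1 went from 28.4 ± 7.33 to 103 ± 47.2 CPM (log2 1.85 ± 0.431) and Igtp from 396 ± 49.2 to 829 ± 360 CPM (log2 1.06 ± 0.280). The camera test of this list gave adjusted p = 2.88e-13 with the preset correlation, and adjusted p = 0.303 with an estimated correlation. Ifng, the gene of interferon gamma itself, is not in the list and was not higher. It lay at 57.0, 37.7 and 40.4 CPM in naive and 40.9, 39.0 and 35.8 CPM in infected Cre-negative replicates 0, 1 and 2.

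Other T cell programmes were called by the same camera test in these Cre-negative mice. Of 17 type 2 helper genes, 10 were above 0 and 3 rose when adjusted over the list alone, Il4, Il5 and Il17rb, with 0 called over all genes (adjusted p = 0.00148; adjusted p = 0.436 with an estimated correlation). Il17rb, a subunit of the receptor for IL-25, lay at 7.32 ± 2.95 CPM in naive and 35.1 ± 21.2 CPM in infected libraries. Il4 had 6.23 ± 3.28 and 33.8 ± 16.7 CPM, a log2 difference of 2.44 as deposited and 2.02 with the infected values exchanged between genotypes. Il5 had no count in the naive libraries, and 13.4 ± 4.83 CPM after infection was at least 68.5-fold higher as deposited, against a floor of 3 counts over the group, while the infected level was 5.06 ± 4.79 CPM with the values exchanged. Of 25 genes of T cell receptor signalling and the immediate early response, 20 were below 0, with a median of -0.17, and 1 fell when adjusted over the list alone (adjusted p = 0.00146; adjusted p = 0.436 with an estimated correlation). That gene was Tnfaip3, an inhibitor of NF-kB signalling, at 3764 ± 652 CPM in naive and 2542 ± 206 CPM in infected libraries. These 2 lists and the interferon gamma list kept their calls when each library was left out in turn. The T cell receptor list shares Fos, Jun, Egr1 and Ier2 with the heat shock and dissociation list, which was also lower, as given below.

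Proliferation and type I interferon genes were also called higher after infection in Cre-negative mice. Of 36 cell cycle genes, 27 were above 0 with a median of 0.72, and 0 passed singly, over the list alone or over all genes (camera adjusted p = 0.00146; adjusted p = 0.436 with an estimated correlation). Ccna2, which drives entry into mitosis, lay at 4.74 ± 2.20 CPM in naive and 21.1 ± 11.6 CPM in infected libraries. The cell cycle call ended without naive replicate 0 (adjusted p = 0.0917) or infected replicate 1 (adjusted p = 0.149). Of 28 type I interferon response genes, 23 were above 0 with a median of 0.42 and 0 passed singly (adjusted p = 0.00148; adjusted p = 0.487 with an estimated correlation). This call ended without naive replicate 2 (adjusted p = 0.347) or infected replicate 2 (adjusted p = 0.127). Of 32 oxidative phosphorylation genes, 23 were above 0 with a median of 0.20 and 0 passed singly (adjusted p = 0.0453; adjusted p = 0.487 with an estimated correlation). That call ended without naive replicate 0 (adjusted p = 0.43), naive replicate 1 (adjusted p = 0.299), infected replicate 0 (adjusted p = 0.0592) or infected replicate 2 (adjusted p = 0.32). With a trend on gene length removed from each library, the oxidative phosphorylation median was -0.02 (adjusted p = 0.969), so this list moved no more than other genes of its length.

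Several T cell lists were called lower or higher only as long as naive Cre-negative replicate 2, a library of low complexity, stayed in. Of 19 type 17 helper genes, 15 were below 0 with a median of -0.81 and 0 passed singly, such as Ccl20, a chemokine for CCR6-bearing cells, at 111 ± 56.9 CPM in naive and 29.1 ± 0.891 CPM in infected libraries (camera adjusted p = 0.00115; adjusted p = 0.48 with an estimated correlation). Without that library the type 17 adjusted p was 0.344. Of 17 tissue residency and gut homing genes, 15 were below 0 with a median of -0.31, led by the gut homing receptor Ccr9 at 126 ± 91.4 and 44.0 ± 21.9 CPM (adjusted p = 0.013; adjusted p = 0.436 with an estimated correlation), and the adjusted p was 0.522 without that library and 0.125 without infected replicate 2. Of 16 genes of naive and central memory cells, 14 were above 0 with a median of 0.50, led by the transcription factor Klf2 at 315 ± 177 and 508 ± 113 CPM (adjusted p = 0.00371; adjusted p = 0.487 with an estimated correlation), and without that library the direction turned (adjusted p = 0.873). Of 18 Notch pathway genes, 15 were below 0 with a median of -0.38, led by the receptor Notch1 at 185 ± 61.7 and 114 ± 28.9 CPM (adjusted p = 0.0143; adjusted p = 0.303 with an estimated correlation), and the adjusted p was 0.113 without that library and 0.0511 without infected replicate 0. In each of these 4 lists, 0 genes passed singly, over the list alone or over all genes.

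Lists of metabolism and stress were called lower after infection in Cre-negative mice, again with 0 genes passing singly. Of 19 cholesterol synthesis genes, 13 were below 0 with a median of -0.29, such as the squalene epoxidase Sqle at 112 ± 35.7 CPM in naive and 60.4 ± 14.8 CPM in infected libraries (camera adjusted p = 0.0324; adjusted p = 0.431 with an estimated correlation). Of 17 unfolded protein response genes, 14 were below 0 with a median of -0.18 (adjusted p = 0.0143; adjusted p = 0.436 with an estimated correlation). Of 16 heat shock and dissociation genes, 16 were below 0 with a median of -0.52, led by the stress factor Atf3 at 420 ± 192 and 120 ± 37.5 CPM (adjusted p = 0.0059; adjusted p = 0.487 with an estimated correlation). The cholesterol call ended without naive replicate 1 (adjusted p = 0.0971), naive replicate 2 (adjusted p = 0.216) or infected replicate 0 (adjusted p = 0.168). It also ended with the length trend removed (adjusted p = 0.0924), although its median was then -0.34. The unfolded protein call ended without naive replicate 0 (adjusted p = 0.149), naive replicate 2 (adjusted p = 0.0548) or infected replicate 1 (adjusted p = 0.143). The heat shock call ended without naive replicate 0 (adjusted p = 0.967) or infected replicate 1 (adjusted p = 0.193). Naive replicate 0 held 3.68% of its counts in these genes, the highest share of any library.

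Of the lists for other cell types, the epithelial, stromal, and basophil and mast cell lists were called higher in the infected Cre-negative libraries. Of 21 epithelial genes, 21 were above 0 with a median of 2.41, such as the keratin gene Krt19 at 2.97 ± 2.75 CPM in naive and 32.2 ± 22.4 CPM in infected libraries, and 0 passed singly (camera adjusted p = 3.54e-07; adjusted p = 0.431 with an estimated correlation). Of 11 stromal genes, 10 were above 0 with a median of 3.30, or 3.07 with the 5 genes that a whole group lacked at their bound, and 0 passed singly (adjusted p = 0.00783; adjusted p = 0.481 with an estimated correlation). The stromal call ended without infected replicate 0 (adjusted p = 0.255). Of 6 basophil and mast cell genes with enough counts, 4 were above 0, and Hdc and Il4 rose when adjusted over the list alone (adjusted p = 0.0087; adjusted p = 0.303 with an estimated correlation), a call that ended without infected replicate 0 (adjusted p = 0.0517). The plasma cell list was not called, with 10 of 12 genes below 0 and a median of -0.99 (adjusted p = 0.165; adjusted p = 0.487 with an estimated correlation). Plasma cell genes held 0.321 ± 0.214% of the counts in naive and 0.129 ± 0.0507% in infected Cre-negative libraries, and 0.252 ± 0.101% and 0.103 ± 0.0154% in Cre-positive ones.

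No single gene passed edgeR's test at an adjusted p of 0.05 over all 12633 genes between naive and infected Cre-negative mice, with 0 calls, 546 genes (4.32%) at an unadjusted p under 0.05, 18 calls by DESeq2 (15 rose, 3 fell), 1 by limma-voom with quality weights and 0 by limma-trend on the normalized values. The genes with the smallest p were Hdc, Spty2d1, Lars2, Prrc2c and Gm17767. Hdc, which encodes histidine decarboxylase, the enzyme that makes histamine, lay at 8.92 ± 2.32 CPM in naive and 53.0 ± 12.3 CPM in infected libraries (log2 2.57 ± 0.409, edgeR adjusted p = 0.295). Lars2, a mitochondrial leucyl-tRNA synthetase, lay at 95.5 ± 10.4 and 203 ± 14.9 CPM (log2 1.09 ± 0.201, edgeR adjusted p = 0.728). Spty2d1, a histone chaperone, lay at 614 ± 132 and 278 ± 14.5 CPM (edgeR adjusted p = 0.295), and Prrc2c had a log2 fold change of 0.94 ± 0.193. Gm17767 had 1 count over the naive and 74 over the infected libraries. Gzmb, the granule protease of cytotoxic cells, lay at 723 ± 285 and 1501 ± 200 CPM (log2 1.05 ± 0.336, edgeR adjusted p = 1). Il17a lay at 39.1 ± 44.6 and 12.2 ± 4.37 CPM, without passing, and its naive mean rests on replicate 2 (9.35, 17.5 and 90.3 CPM in replicates 0, 1 and 2). In simulated libraries with changes planted in the infected Cre-positive group, 12% of the genes changed 2-fold and 50% of those changed 4-fold were recovered. The planted genes had a mean of at least 4 CPM.

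The second comparison puts the same question to Cre-positive mice, in which Notch signalling is blocked in basophils. Here 69 of 12633 genes changed, 26 rising and 43 falling. The rise of Hdc passed the test, from 12.9 ± 4.42 CPM in naive to 100 ± 40.7 CPM in infected libraries (log2 2.95 ± 0.411, edgeR adjusted p = 0.0143). Lars2 rose from 105 ± 9.69 to 468 ± 138 CPM (log2 2.16 ± 0.207, edgeR adjusted p = 0.00339), and this call held when each library was left out in turn, while that of Hdc ended without naive replicate 0, 1 or 2 (adjusted p = 0.0624, 0.0734 and 0.0671). Of the mitochondrial genome, the genes mt-Nd6, mt-Nd4, mt-Cytb, mt-Rnr2 and mt-Co1 rose by log2 2.42 ± 0.429, 1.96 ± 0.366, 1.93 ± 0.364, 1.87 ± 0.360 and 1.76 ± 0.338 (edgeR adjusted p from 0.0429 to 0.0477), for example mt-Co1 from 2060 ± 218 to 6963 ± 3330 CPM. Without infected replicate 1, the library with the highest mitochondrial share (4.17%), the adjusted p of these mitochondrial genes was 0.0585 to 0.0781, and without any 1 naive replicate it was 0.104 to 0.181. In the antisense and overlapping parts of the mitochondrial genome, reads of neighbouring genes cannot be told apart without strand.

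The remaining named rises in Cre-positive mice were Neb, Arl4c, AU020206 and Cox8a. Neb, known for the giant muscle protein nebulin, rose from 101 ± 50.8 to 370 ± 47.2 CPM (log2 1.88 ± 0.364). Arl4c, a small GTPase, rose from 23.7 ± 8.72 to 85.3 ± 16.8 CPM (log2 1.85 ± 0.328), and the long noncoding RNA AU020206 rose from 141 ± 48.6 to 474 ± 37.6 CPM (log2 1.75 ± 0.238). Cox8a, a subunit of cytochrome c oxidase, rose from 132 ± 7.44 to 249 ± 22.0 CPM (log2 0.92 ± 0.162, edgeR adjusted p = 0.0426). Without naive replicate 1 the adjusted p was 0.144 for Neb, 0.144 for Arl4c, 0.0818 for AU020206 and 0.139 for Cox8a, and only AU020206 kept its call without each other library. For the others it was 0.0535, 0.111 and 0.1 without naive replicate 0, and 0.181, 0.0588 and 0.165 without naive replicate 2. Without infected replicate 1 it was 0.0549, 0.0564 and 0.0549, and Neb also lost its call without infected replicate 0 (0.0587) or 2 (0.0546).

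The falls were led by genes whose transcripts were missing from the infected Cre-positive libraries. With 0 counts in the 3 infected libraries, Cmtr2, an mRNA cap methyltransferase, was at least 85.9-fold lower, the mitochondrial carrier Slc25a29 at least 77.0-fold lower, the receptor kinase Tyro3 at least 59.6-fold lower, Tmem106a at least 56.8-fold lower and Pogk at least 40.2-fold lower, each against a floor of 3 counts over the group. Their naive levels were 20.1 ± 7.90, 19.5 ± 3.25, 14.3 ± 4.92, 14.1 ± 3.56 and 10.5 ± 5.13 CPM. That floor covers counting error only, not transcripts lost before sequencing. Of 11376 genes with a mean of at least 2 CPM in the other groups, 146 had 0 counts in all 3 infected Cre-positive libraries. Such genes also occurred in each other group. They numbered 72 of 11617 in naive Cre-negative, 49 of 11598 in naive Cre-positive and 30 of 11571 in infected Cre-negative libraries. Zfp995 had 218 counts over the naive and 1 over the infected Cre-positive libraries, Abcb10 had 145 and 1, and Nmnat3, an enzyme of NAD synthesis, had 164 and 2. B3galt5, a galactosyltransferase, fell from 17.7 ± 13.0 to 0.376 ± 0.147 CPM, and Zfp689 fell from 30.1 ± 11.9 to 1.08 ± 0.946 CPM. Among abundant genes, Tnfaip3 fell from 3605 ± 32.7 to 1896 ± 217 CPM (log2 -0.93 ± 0.139, edgeR adjusted p = 0.0207). The calls of Slc25a29 and Tmem106a held when each library was left out in turn, and that of Tnfaip3 ended without naive replicate 0, 1 or 2 (adjusted p = 0.0624, 0.0807 and 0.0671). Without naive replicate 1 the adjusted p was 0.0734 for Cmtr2, 0.0747 for Tyro3, 0.0807 for Pogk, 0.0818 for Zfp995, 0.0807 for Abcb10, 0.132 for Nmnat3, 0.139 for B3galt5 and 0.132 for Zfp689. Without naive replicate 0 it was 0.0535, 0.0602, 0.0602, 0.0814, 0.0624, 0.104, 0.109 and 0.0932 in the same order, so none of these 8 calls held.

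**Figure D3:**
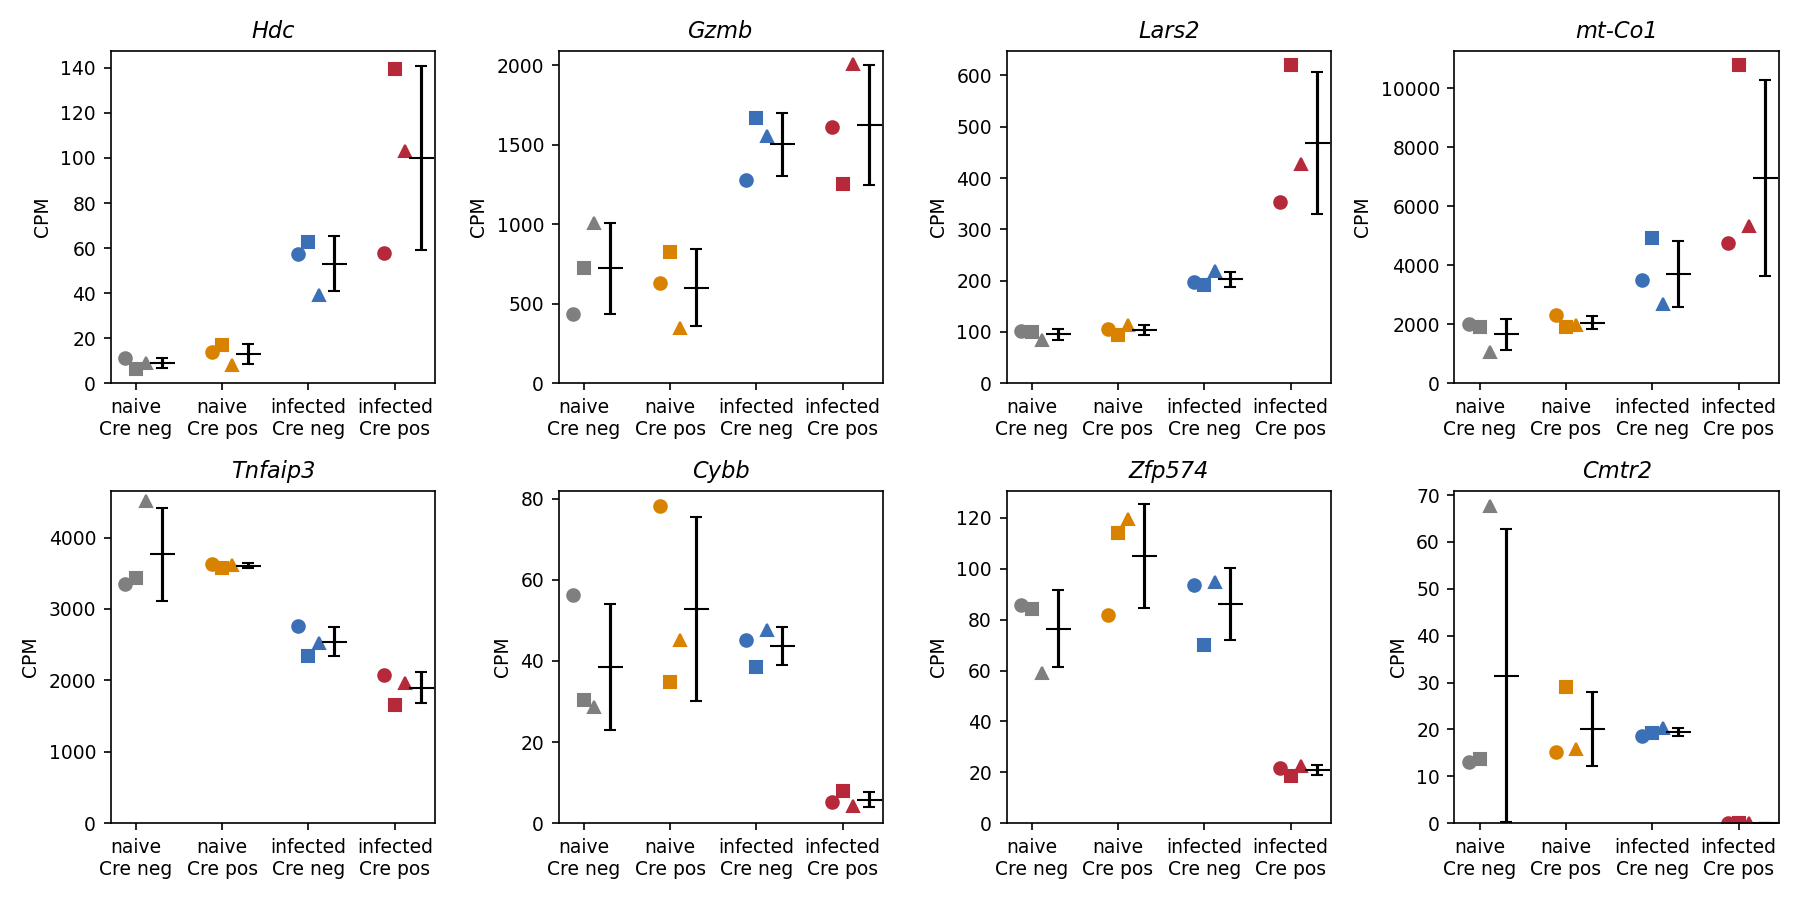
CPM of Hdc, Gzmb, Lars2, mt-Co1, Tnfaip3, Cybb, Zfp574 and Cmtr2 in each of the 12 libraries by group, with symbols for the replicate number (circle 0, square 1, triangle 2) and bars for mean ± SD of 3 libraries. Cmtr2 has 0 counts in the 3 infected Cre-positive libraries, and naive Cre-negative replicate 2 stands far above the other libraries for that gene.

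By lists, the type 2 and cytokine genes were called higher with infection in Cre-positive mice. Of 17 type 2 helper genes, 16 were above 0 with a median of 0.44 and 2 rose when adjusted over the list alone, Il4 and Il5, with 0 over all genes (camera adjusted p = 0.00198; adjusted p = 0.492 with an estimated correlation). Without naive replicate 2 the type 2 adjusted p was 0.0513. Il4 had 3.72 ± 2.61 CPM in naive and 28.1 ± 9.48 CPM in infected libraries, a log2 difference of 2.90 as deposited and 3.29 with the infected values exchanged between genotypes (edgeR adjusted p = 0.0728 and 0.0524). Il5 was at least 24.3-fold and Il13 at least 6.08-fold higher after infection as deposited, from infected levels of 5.58 ± 4.95 and 1.31 ± 0.887 CPM that become 14.7 ± 5.32 and 5.63 ± 1.34 CPM with the values exchanged, neither passing the test over all genes. Areg, an epidermal growth factor family member, lay at 250 ± 81.6 and 466 ± 87.0 CPM (log2 0.90 ± 0.342, edgeR adjusted p = 0.235), while Gata3, the transcription factor of type 2 cells, lay at 123 ± 36.2 and 129 ± 3.70 CPM. Of 23 secreted cytokine genes, 18 were above 0 with a median of 0.32 and the same Il4 and Il5 rose when adjusted over the list alone (adjusted p = 0.00231; adjusted p = 0.31 with an estimated correlation).

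Interferon and respiration genes were called higher in the same comparison and sterol genes lower. Of 24 interferon gamma response genes, 21 were above 0 with a median of 0.34, and Iigp1 (82.2 ± 22.3 to 188 ± 72.3 CPM) and the immunoproteasome subunit gene Psmb9 (198 ± 26.8 to 327 ± 45.3 CPM) rose when adjusted over the list alone, with 0 over all genes (camera adjusted p = 0.00242; adjusted p = 0.775 with an estimated correlation). Of 32 nuclear oxidative phosphorylation genes, 1 rose over all genes, and 11 rose and 2 fell when adjusted over the list alone (adjusted p = 0.00198; adjusted p = 0.492 with an estimated correlation). The risers included Cox8a and Ndufa1 (75.7 ± 1.16 to 141 ± 18.7 CPM), and the fallers were Atp5f1a and Atp5f1b, which encode the catalytic core of ATP synthase. Both calls ended without infected replicate 1 (adjusted p = 0.124 and 0.0525). Short genes were higher in general here, with a median log2 fold change of 0.27 up to 2497 bases, and with the length trend removed the oxidative phosphorylation median was 0.27 (adjusted p = 0.0341; adjusted p = 0.837 with an estimated correlation). Of 19 cholesterol synthesis genes, 16 were below 0 with a median of -0.55 and 0 passed singly, such as Insig1, a sterol sensor of the endoplasmic reticulum, at 204 ± 12.3 and 103 ± 49.0 CPM (adjusted p = 0.0264; adjusted p = 0.321 with an estimated correlation). The cholesterol call ended without naive replicate 2 (adjusted p = 0.0513), infected replicate 0 (adjusted p = 0.0649) or infected replicate 1 (adjusted p = 0.0879). It also ended with the length trend removed (adjusted p = 0.117), where its median was -0.39.

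The epithelial and the basophil and mast cell lists were called higher with infection in Cre-positive mice as well. Of 21 epithelial genes, 21 were above 0 with a median of 2.92 and 5 rose when adjusted over the list alone, with 0 over all genes (camera adjusted p = 3.33e-09; adjusted p = 0.321 with an estimated correlation). They included Lgals4, an intestinal galectin, at 19.6 ± 11.9 and 100 ± 63.8 CPM, and the goblet cell gene Clca1 at 0.158 ± 0.274 and 79.5 ± 124 CPM. Of 6 basophil and mast cell genes, 5 were above 0 and 1 rose over all genes, Hdc, with Il4 added when adjusted over the list alone (adjusted p = 0.0228; adjusted p = 0.321 with an estimated correlation), a list call that ended without infected replicate 2 (adjusted p = 0.157).

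The 69 calls came from edgeR's test over 12 libraries, with 1951 genes at an unadjusted p under 0.05. DESeq2 called 792, limma-voom 14, limma-trend 185, a fit of the 6 Cre-positive libraries alone 0 and a replicate block 34, and with DESeq2's size factors in edgeR the calls were 64, of which 31 rose and 33 fell. Without naive replicate 0, 1 or 2 the counts were 7, 6 and 14, without infected replicate 0 or 2 they were 126 and 196, and without the 2 libraries of low complexity 195 (59 rose, 136 fell), of which 55 were shared. With the length trend removed, 25 genes were called (14 rose, 11 fell), 22 of them among the 69. Of the 26 rises 11 stayed called, with a median log2 of 1.60 before and 1.52 after, and of the 43 falls 11 stayed called, with -1.35 and -1.19.

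The third comparison asks how infected Cre-positive and Cre-negative mice differ. In it, 5 of 12633 genes were called, 5 lower and 0 higher in Cre-positive mice. Cybb, which encodes the catalytic subunit of the phagocyte NADPH oxidase, lay at 5.83 ± 1.89 CPM in Cre-positive against 43.8 ± 4.66 CPM in Cre-negative libraries (log2 -2.93 ± 0.427, edgeR adjusted p = 0.0496). The zinc finger gene Zfp574 lay at 20.9 ± 2.02 against 86.1 ± 14.1 CPM (log2 -2.04 ± 0.249, edgeR adjusted p = 0.0192). With 0 counts in the infected Cre-positive libraries, Tmem106a was at least 80.6-fold lower (edgeR adjusted p = 0.0176), Cmtr2 at least 80.6-fold lower (adjusted p = 0.0496) and Slc25a29 at least 46.8-fold lower (adjusted p = 0.0251), against a floor of 3 counts over the group. The floor again covers counting error only, not transcripts lost before sequencing. In Cre-negative libraries Tmem106a lay at 20.3 ± 5.59 and Cmtr2 at 19.4 ± 0.863 CPM, and Slc25a29 had 158 counts. Without infected Cre-negative replicate 0 the adjusted p was 0.205 for Cybb, 0.0898 for Zfp574, 0.0898 for Tmem106a, 0.202 for Cmtr2 and 0.0898 for Slc25a29. Without Cre-negative replicate 1 it was 0.162, 0.0576, 0.0576, 0.162 and 0.0922, and without replicate 2 it was 0.182, 0.0975, 0.0548, 0.182 and 0.0548. Cybb and Cmtr2 also lost their calls without infected Cre-positive replicate 0 (0.0639 for both).

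Cytokines and lineage factors did not pass between infected genotypes. Il4 had 33.8 ± 16.7 CPM in Cre-negative and 28.1 ± 9.48 CPM in Cre-positive libraries as deposited, and 25.2 ± 6.63 and 36.6 ± 16.1 CPM with the infected values exchanged. Il5 had 13.4 ± 4.83 and 5.58 ± 4.95 CPM as deposited and 5.06 ± 4.79 and 14.7 ± 5.32 CPM exchanged, and Il13 had 5.15 ± 1.23 and 1.31 ± 0.887 CPM as deposited and 1.20 ± 0.869 and 5.63 ± 1.34 CPM exchanged. The log2 differences were -0.27, -1.27 and -1.98 as deposited (edgeR adjusted p = 0.951, 0.83 and 0.75) and 0.54, 1.55 and 2.23 exchanged (edgeR adjusted p = 0.868, 0.77 and 0.695). The type 2 list, which contains these genes, was not called as deposited (camera adjusted p = 0.818) and was called higher in Cre-positive libraries with the exchange (adjusted p = 0.0312; adjusted p = 0.905 with an estimated correlation). Areg lay at 297 ± 63.5 CPM in Cre-negative and 466 ± 87.0 CPM in Cre-positive libraries (edgeR adjusted p = 0.598), Il10 at 688 ± 51.8 and 983 ± 449 CPM, and Il1rl1, the IL-33 receptor, at 104 ± 72.9 and 123 ± 41.1 CPM. Ifng lay at 38.6 ± 2.57 and 39.0 ± 17.9 CPM, Tbx21 at 150 ± 19.0 and 136 ± 11.8 CPM, and Gzmb at 1501 ± 200 and 1623 ± 379 CPM. Il17a lay at 12.2 ± 4.37 and 20.7 ± 7.11 CPM, Il22 at 26.2 ± 6.21 and 23.4 ± 19.9 CPM, Bcl6 at 56.6 ± 14.1 and 39.3 ± 17.5 CPM, Il21 at 50.8 ± 39.3 and 45.7 ± 42.9 CPM, and Mki67 at 23.4 ± 13.1 and 26.7 ± 33.4 CPM. Il9 had 1 count over the infected libraries and was not tested.

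Proliferation and interferon lists were called lower in infected Cre-positive than in infected Cre-negative mice. Of 36 cell cycle genes, 29 were below 0 with a median of -0.55, such as Mcm7, a subunit of the replicative helicase, at 61.2 ± 19.2 against 110 ± 10.1 CPM (camera adjusted p = 0.019; adjusted p = 0.938 with an estimated correlation). Of 28 type I interferon response genes, 25 were below 0 with a median of -0.60, such as Irf7 at 211 ± 27.3 against 363 ± 158 CPM (adjusted p = 0.0114; adjusted p = 0.938 with an estimated correlation). Of 24 interferon gamma response genes, 23 were below 0 with a median of -0.40, such as the peptide transporter gene Tap1 at 536 ± 59.2 against 767 ± 155 CPM (adjusted p = 0.019; adjusted p = 0.938 with an estimated correlation). In each of the 3 lists, 0 genes passed singly, over the list alone or over all genes. The cell cycle call ended without infected Cre-negative replicate 1 (adjusted p = 0.504) or 2 (0.127) and without infected Cre-positive replicate 0 (0.0968) or 2 (0.19). Both interferon calls ended without Cre-negative replicate 2 (adjusted p = 0.408 for type I and 0.659 for gamma) and without Cre-positive replicate 2 (0.405 and 0.485). The gamma call also ended without Cre-positive replicate 0 (0.0968) and with the length trend removed (0.218), where its median was -0.19.

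Type 17, respiration and epithelial lists were called higher in infected Cre-positive mice. Of 19 type 17 helper genes, 14 were above 0 with a median of 0.57 and 0 passed singly, such as the transcription factor gene Maf at 253 ± 44.9 against 144 ± 57.0 CPM (camera adjusted p = 0.0357; adjusted p = 0.938 with an estimated correlation), a call that ended without Cre-negative replicate 2 (adjusted p = 0.386), Cre-positive replicate 0 (0.192) or Cre-positive replicate 2 (0.509), and with the length trend removed (0.196). Of 32 oxidative phosphorylation genes, 23 were above 0 with a median of 0.27, and 3 rose and 2 fell when adjusted over the list alone, with 0 over all genes (adjusted p = 0.00756; adjusted p = 0.938 with an estimated correlation). Of 21 epithelial genes, 20 were above 0 with a median of 1.55 and 0 passed singly (adjusted p = 0.0114; adjusted p = 0.938 with an estimated correlation). The respiration call ended without Cre-positive replicate 1 (adjusted p = 0.167), and the epithelial call without Cre-positive replicate 1 (0.329) or Cre-negative replicate 2 (0.429). With the length trend removed the adjusted p was 0.0196 for respiration, with a median of 0.25 (adjusted p = 0.993 with an estimated correlation), and 0.117 for epithelial genes. The median was then 1.63 for epithelial and 0.49 for type 17 genes, so these 2 calls ended while the folds changed little. In that setting 4 single genes were called, 3 of them among the 5. The 5 single genes were called by edgeR beside 1180 genes at an unadjusted p under 0.05; DESeq2 called 235 (69 rose, 166 fell), limma-trend 15, limma-voom 0, and edgeR 3 with DESeq2's size factors, 0 with a replicate block and 0 with the 6 infected libraries alone. The count was 0 without each of the infected Cre-negative replicates 0, 1 and 2, and 9, 38 and 75 without Cre-positive replicates 0, 1 and 2; without the 2 libraries of low complexity it was 8, of which 3 were shared.

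The fourth comparison asks whether the genotypes differed before infection. Naive Cre-positive libraries held more of the transcripts of naive and central memory cells as a list, with 16 of 16 genes above 0 and a median of 0.71, such as Ccr7, the lymph node homing receptor, at 2283 ± 1260 against 1101 ± 649 CPM (camera adjusted p = 4.58e-06; adjusted p = 0.712 with an estimated correlation). Tissue residency genes were lower, with 16 of 17 below 0 and a median of -0.37, such as Ccr9 at 38.2 ± 5.85 against 126 ± 91.4 CPM (adjusted p = 0.000156; adjusted p = 0.579 with an estimated correlation). Of 19 type 17 helper genes 17 were below 0 (median -0.50, adjusted p = 0.00387; adjusted p = 0.712 with an estimated correlation), and of 21 regulatory T cell genes 17 were below 0 (median -0.31, adjusted p = 0.0186; adjusted p = 0.712 with an estimated correlation). Of 23 secreted cytokine genes 17 were below 0 (median -0.26, adjusted p = 0.0217; adjusted p = 0.579 with an estimated correlation), and of 16 heat shock and dissociation genes 15 were below 0 (median -0.68, adjusted p = 0.00387; adjusted p = 0.712 with an estimated correlation). In each of the 6 lists, 0 genes passed singly.

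The first 5 of these naive lists were not called without naive Cre-negative replicate 2, the library of lowest complexity, with adjusted p = 0.208 for naive and central memory, 0.0575 for tissue residency, 0.906 for type 17, 0.906 for regulatory T cell and 0.0575 for secreted cytokine genes. The type 17, regulatory T cell and cytokine calls also ended without naive Cre-positive replicate 2 (adjusted p = 0.472, 0.546 and 0.377), and the cytokine call without naive Cre-negative replicate 0 (0.175). The heat shock call ended without naive Cre-negative replicate 0 (adjusted p = 0.899) or naive Cre-positive replicate 1 (0.138). No single gene passed edgeR's test, with 0 calls, 253 genes (2%) at an unadjusted p under 0.05, 3 calls by DESeq2, and 0 by limma-voom and limma-trend. The smallest p values belonged to Ciita, Synrg, Nsl1, A530083M17Rik and Ccl6, of which Synrg lay at 57.3 ± 6.02 against 23.4 ± 5.59 CPM (log2 1.29 ± 0.333, edgeR adjusted p = 1).

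The fifth comparison asks whether infection acted differently in the 2 genotypes. The genes with the smallest p for this difference were Tmem106a, Zfp574, Slc25a29, Cybb and Tyro3, and none passed. Zfp574 had an interaction of log2 -2.50 ± 0.341 (edgeR adjusted p = 0.06) and Cybb of -3.38 ± 0.571 (edgeR adjusted p = 0.231). The adjusted p was 0.06 for Tmem106a, 0.0757 for Slc25a29 and 0.231 for Tyro3. EdgeR called 0 of 12633 genes, with 802 at an unadjusted p under 0.05, DESeq2 63 (19 higher, 44 lower), limma-trend 3 and limma-voom 0, and edgeR called 4 without infected Cre-positive replicate 1 and 15 without replicate 2.

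By lists, the response to infection differed between genotypes for 8 of 33 lists with the preset correlation and for 0 with an estimated one (smallest adjusted p = 0.904). With the infected values of Il4, Il5 and Il13 exchanged it was 10 lists, adding the type 2 (adjusted p = 0.0281; adjusted p = 0.87 with an estimated correlation) and secreted cytokine lists (adjusted p = 0.00394; adjusted p = 0.34 with an estimated correlation). Genes of naive and central memory cells had a lower infection effect in Cre-positive mice, with 16 of 16 interactions below 0 and a median of -1.34, for example Ccr7 at log2 -2.17 ± 0.769. Type 17 genes went the other way, with 18 of 19 above 0 and a median of 0.85, for example Maf at 1.37 ± 0.443. Cell cycle genes had 27 of 36 below 0 (median -0.69) and type I interferon response genes 24 of 28 below 0 (median -0.76). Regulatory T cell, tissue residency, oxidative phosphorylation and epithelial genes had medians of 0.28, 0.53, 0.19 and 1.10. Each call ended without at least 1 library. Without infected Cre-positive replicate 2 the adjusted p was 0.0535 for naive and central memory, 0.0535 for type 17, 0.0585 for cell cycle, 0.195 for type I interferon, 0.0818 for regulatory T cell, 0.217 for tissue residency and 0.0585 for oxidative phosphorylation genes, and without infected Cre-negative replicate 2 it was 0.394 for epithelial genes. Without the 2 libraries of low complexity the camera adjusted p was 0.178 for naive and central memory, 0.291 for type 17 and 0.0764 for cell cycle genes. In that setting it was 0.291 for type I interferon, 0.947 for regulatory T cell, and 0.305 for both tissue residency and oxidative phosphorylation genes. Only the epithelial list of the 8 kept its call there. With the length trend removed, the regulatory T cell (adjusted p = 0.056) and epithelial (0.115) calls ended, although their medians were then 0.50 and 1.09. Across all 12633 genes, the infection effects of the 2 genotypes, which share no library, correlated with Pearson's r = 0.176 and Spearman's rho = 0.205; genes are not independent replicates. This r was 0.0954 without infected Cre-positive replicate 1.

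**Figure D4:**
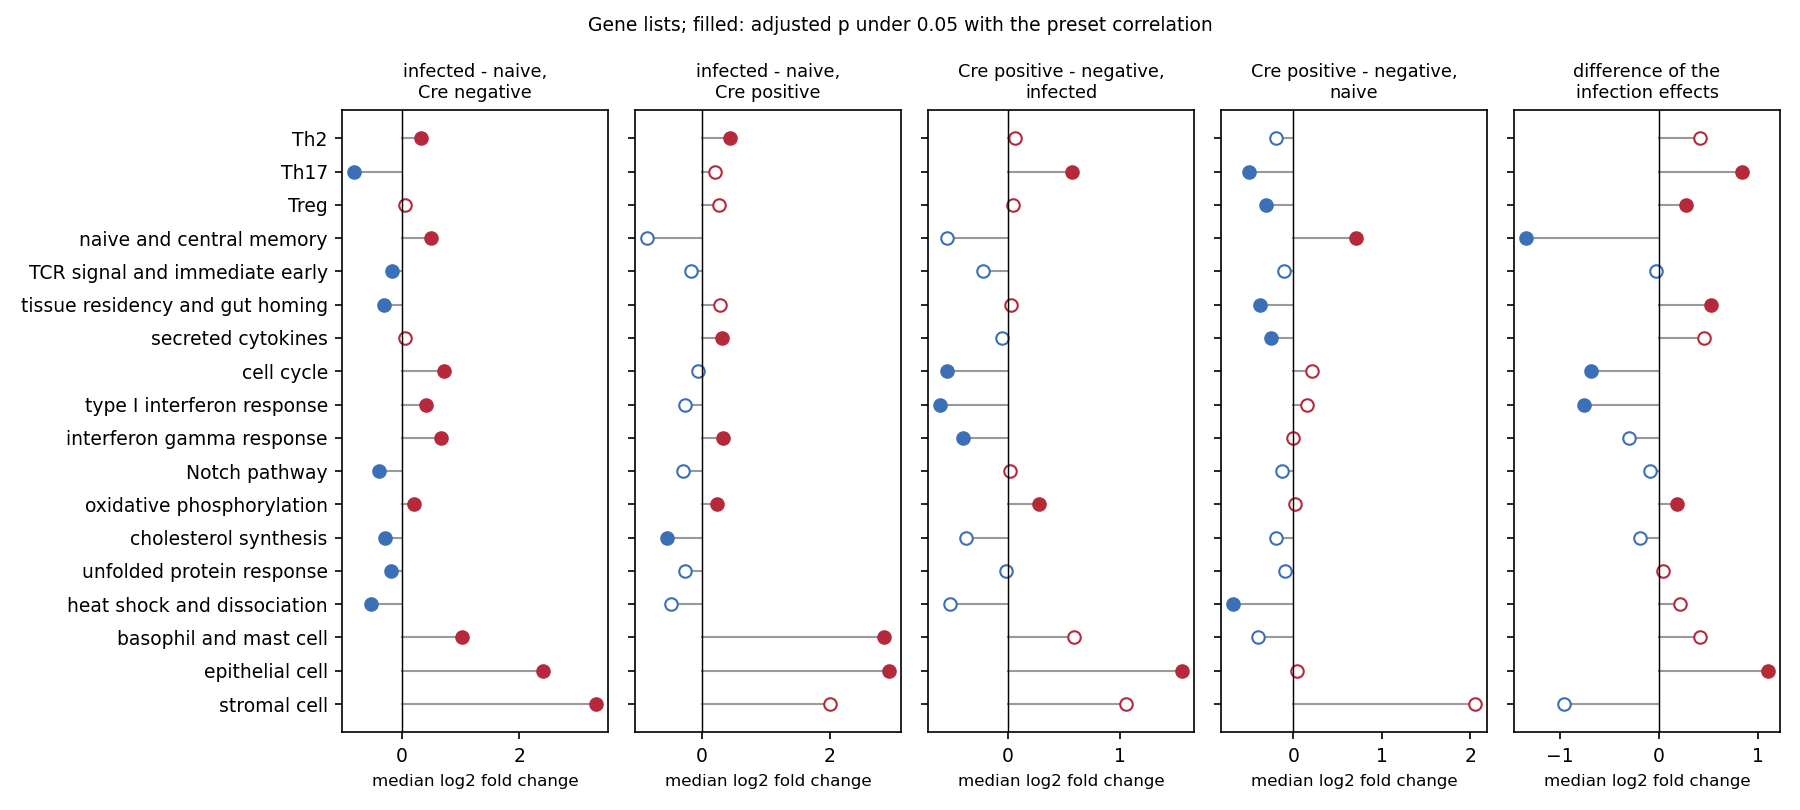
Median log2 fold change of each list called in at least 1 comparison, for the 5 comparisons from left to right, with filled symbols for an adjusted p under 0.05 in the camera test with the preset correlation, red above 0 and blue below. The horizontal scale differs between panels, and with an estimated correlation 0 lists pass in each of the 5 comparisons.

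Genes close to Mcpt8 on chromosome 14 were examined for differences that could travel with the Cre allele. The labels do not say whether that allele lies at Mcpt8, and the check bears on it only if it does. Of 228 tested genes within 10 Mb, 0 were called by edgeR between infected genotypes and 0 between naive ones, against 4 and 0 by DESeq2. EdgeR called only 5 and 0 of the 12405 tested genes elsewhere, so its 0 calls near Mcpt8 were likely beforehand and test little. DESeq2 also called more genes in total, as given above. At an unadjusted p under 0.05 there were 13 (5.7%) near Mcpt8 and 9.41% elsewhere between infected genotypes (Fisher's exact test, two-sided, p = 0.0649), and 6 (2.63%) against 1.99% between naive ones (p = 0.468).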

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

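The tests of the table ratios, of random loss and of the length trend on the falls were chosen only after the results were seen, and 3 of them replaced or tightened a first version, as stated below; the tests of the interferon list and of other splits were set down before they were run.

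In Il4, Il5 and Il13, the raw and normalized values of the infected libraries carry the size factor of the other genotype. Rounding around the library's own factor is argued against, since 0 of 18 infected ratios equalled it, while 18 of 18 equalled the factor of the same-numbered library of the other genotype. Whether the counts themselves were exchanged or only the factor was wrong cannot be told from the ratios. The other 14 tested type 2 genes had a median log2 difference of 0.265 between infected Cre-positive and Cre-negative libraries, 11 of 14 above 0. Their camera list test did not pass. Their direction could not decide the question in any case, since it does not show where the values of Il4, Il5 and Il13 belong. A first rule on the lower quartile alone (0.00675, barely above 0) would have favoured exchanged counts, and the list test was added to it after that outcome was seen. No biological explanation was tested, and the infected genotype direction of these 3 genes may be opposite to the tables.

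Many genes had 0 counts in all 3 infected Cre-positive libraries, and 43 genes fell with infection there. Random loss of transcripts in libraries of low complexity may account for part of the first: 150 such genes stood against 55.4 expected from independent losses, a ratio of 2.71 (95% 2.29 to 3.18), and trios that mix 2 of these libraries with naive Cre-negative replicate 2, also of low complexity, gave 2.62, 2.62 and 2.24; this concerns their number, not single genes such as Cmtr2, which had 353 counts in that naive library. A first version compared the group with the other 3 groups (2.76 against 8.22, 7.93 and 9.26) and also favoured loss, but was replaced because that ratio falls with a higher loss rate by construction. A smooth trend on gene length accounted for little of the size of the falls. Their median log2 fold change was -1.35 as fitted (quartiles -4.02 and -1.07) and -1.19 with the length trend removed (-3.78 and -0.873). That trend was small, with medians of 0.27 for short and -0.11 for long genes. Falls picked for their size could thus hardly turn positive, and that 43 of 43 stayed below 0 tests nothing. A first criterion, whether most calls stay, had favoured length bias, since 11 of 43 stayed called. The median edgeR adjusted p moved from 0.0439 to 0.071 while the folds changed little. Whether length helped these genes to be called stays open. An effect of genotype or infection on these genes stays open.

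The interferon gamma list was higher with infection in Cre-negative libraries. In cells sorted as CD4+, the list's summed CPM was higher by 10.4 times as much as that of the epithelial list (3114 against 299.9 CPM). The rise was larger in 9 of 9 pairings, which reuse the same libraries. The naive means were 5929 ± 128 CPM for the interferon gamma list and 125 ± 60.7 CPM for the epithelial list. RNA of epithelial cells could account for the rise only if such cells hold far more of these transcripts than of their marker genes. Their level in epithelial cells was not measured, so the test cannot exclude it. A smooth trend on gene length did not account for the list's median, 0.69 with the trend removed against 0.674 as fitted. That trend was small here, with medians of 0.153 for short and -0.0163 for long genes. A response to infection stays open as a hypothesis, as do other mixtures of T cells, and the call was lost with an estimated correlation (adjusted p = 0.303).

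The difference between genotypes in the response to infection was called by limma's camera test for 8 lists. The adjusted p was 0.00112 for type 17 genes and 0.00124 for naive and central memory genes. It was 0.00901 for cell cycle and 0.00901 for type I interferon response genes. It was 0.0206 for epithelial, 0.0272 for tissue residency, 0.0436 for regulatory T cell and 0.0463 for oxidative phosphorylation genes. With an estimated correlation the adjusted p of each was 0.904. Without infected Cre-positive replicate 2, 1 of 33 lists was called, the epithelial list; without naive Cre-negative replicate 2, 3 were called, as without naive Cre-positive replicate 2, and without infected Cre-negative replicate 2, 4 were called.

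Other splits of the 6 libraries of a comparison are too few, at 10, for a share under 0.05. The real split of naive and infected Cre-positive libraries gave 69 called genes and the highest other split 0, so 1 of 10 splits gave as many. For infected genotypes the values were 5 and 1, again 1 of 10. For infection in Cre-negative mice and for naive genotypes they were 0 and 0, and against a real count of 0 the 10 of 10 splits that gave as many were certain beforehand and test nothing. For the interaction, 60 of 60 random splits by genotype within each infection state gave at least the real count of 0, with a highest of 2, which was likewise certain and tests nothing.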

How the results depend on the processing

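The settings without the 2 low-complexity libraries, with Il4, Il5 and Il13 exchanged and with the length trend removed, and the other fits of the genes near Mcpt8, were chosen after seeing the data. Unless stated, the cause of a difference was not tested. For infection in Cre-negative mice, 0 genes were called by edgeR, and 18 with DESeq2 and 1 with voom; leaving out a library gave 0 to 0. For infection in Cre-positive mice, 69 became 335 at an adjusted p of 0.1, 792 with DESeq2, 14 with voom and 0 with the compared groups alone. It became 34 with the replicate block, 185 with the normalized values and 195 without the low-complexity libraries, and leaving out a library gave 6 to 196. With the compared groups alone, fewer samples estimate the spread, but the spread was also unequal. Chi-square per degree of freedom between replicates was 32.8 to 47.5 in infected and 21.2 to 27.3 in naive Cre-positive libraries. In Cre-negative libraries it was 15.0 to 19.6 in infected and 24.2 to 47.7 in naive ones. A spread shared by all groups may thus be too small for infected Cre-positive libraries. Which of these ended the 69 calls was not tested. For infected genotypes, 5 became 16 at 0.1, 3 with DESeq2's factors, 235 with DESeq2, 0 with voom, 0 with the compared groups alone, 0 with the replicate block, 15 with the normalized values and 8 without the low-complexity libraries; leaving out a library gave 0 to 75. For naive genotypes, 0 became 3 with DESeq2, and leaving out a library gave 0 to 0. For the interaction, 0 became 3 at 0.1, 2 with no filter, 63 with DESeq2 and 3 with the normalized values; leaving out a library gave 0 to 15. Near Mcpt8, DESeq2 called 4 genes between infected genotypes.

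Lists called were 16, 7, 6, 6 and 8 over the 5 comparisons in the order of the report, and 0 in each with an estimated correlation. Leaving out a library gave 11 to 14, 5 to 13, 1 to 10, 3 to 12 and 1 to 9. Without the low-complexity libraries, 3 lists were called for infected genotypes, 3 for naive genotypes and 1 for the interaction. The gene list test of naive and central memory in naive and infected Cre negative libraries turned direction without naive Cre-negative replicate 2 (adjusted p = 0.873, against 1.82e-05 without replicate 1) and without the low-complexity libraries (0.894), and the macrophage and monocyte list between naive genotypes without naive Cre-positive replicate 2 (0.0204, against 0.795 without naive Cre-negative replicate 2). With the length trend removed, 14, 6, 3, 6 and 6 lists were called, all among those above. With DESeq2's factors 164 of the list tests stayed on their side and 1 lost its call; with the exchange 162 stayed and 3 were newly called, the type 2 list between infected genotypes and the type 2 and secreted cytokine lists in the interaction, and 0 lists were called in each comparison with an estimated correlation. Of 4570 values of named genes under the alternatives, 142 changed sign, 0 of them from a called value; with the exchange these were Il4, Il5 and Il13 between infected genotypes and Il5 in the interaction. The correlation of infection effects was 0.256 among genes with a mean log2 CPM of at least 3, and 0.0954 to 0.22 when a library was left out.

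Same-numbered libraries are not paired by the labels. Their deviations from the group means correlated at only -0.00151 to 0.138. Even so, 12 of 12 libraries correlated best, among libraries of other groups, with their own number. The heat shock share was highest in replicate 0 of every group, at 3.68 and 2.00% in naive Cre-negative and Cre-positive and 2.03 and 1.27% in infected ones. A batch shared by number is therefore plausible, and the main tests did not model it. The counts of calls with a replicate block are given above. With the replicate block, 163 list tests stayed on their side and 2 lost their call (oxidative phosphorylation, for infection in Cre-negative mice and for the interaction). Depth limits genes at a few counts, such as Il13 and the genes at 0.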

Other observations

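The genes below were chosen after their values were seen. Among the basophil and mast cell genes, Hdc had the most counts in the infected libraries. It had 142 and 214 counts over the naive Cre-negative and Cre-positive libraries and 715 and 1154 over the infected ones. Mcpt8, the basophil protease after which Mcpt8-Cre is named, had 0, 0, 16 and 0 counts over the 4 groups in that order. Fcer1a, Ms4a2 and Prss34, further basophil or mast cell genes, had 0 counts in each group, and Cpa3, a mast cell protease, had 0, 14, 6 and 20. Mcpt1 had 0, 0, 14 and 2, the chemokine gene Ccl3 had 23, 12, 38 and 92, Cd200r3 had 13, 35, 22 and 28, and Il6 had 26, 2, 18 and 31. Il4, which T cells also express, had 98, 60, 518 and 339 as deposited, subject to the exchange described for its infected values. Kit exceeded Hdc in the naive groups, with 428 and 412 counts, and lay at 23.4 ± 20.6, 22.4 ± 23.5, 7.36 ± 5.53 and 6.72 ± 1.96 CPM (SD, n = 3).

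Cytotoxic genes formed no called list, yet 4 of 15 rose with infection in Cre-positive mice when adjusted over the list alone, Gzma, Gzmb, Nkg7 and Cst7, with 0 over all genes. Gzma and Gzmb encode granule proteases and Nkg7 a granule protein, and their log2 fold changes were 2.76, 1.44 and 1.37. The list's median was -0.28 while its camera test pointed up (limma, adjusted p = 0.707; adjusted p = 0.775 with an estimated correlation). In Cre-negative mice the median was 0.58 and 0 passed (adjusted p = 0.162; adjusted p = 0.436 with an estimated correlation).

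Infected Cre-positive replicate 1 had 1 count of Xist, the RNA of the inactive X chromosome, and 0 counts of Y-linked genes, although it is labelled female. The other 11 libraries had 286 to 702 counts of Xist and 0 of Y-linked genes.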
